A study of Mus musculus with 2 samples.

How the data were processed

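Single-cell RNA was measured in LSK cells, the lineage-negative, Sca-1-positive, Kit-high fraction of mouse bone marrow that holds haematopoietic stem cells (HSCs) and multipotent progenitors. The cells came from young wild-type (WT) mice and from mice that the labels describe as IκB-negative, named IkBKO in the deposited cell table. Per the labels, 30000 sorted cells of each condition were tagged with hashing antibodies and the conditions of 1 replicate were run together in 1 droplet library, so each of the 2 libraries held both genotypes. The labels do not say which IκB genes were altered. Sex-linked RNA differed between the replicates, so these came from different mice. The number of mice in a pool is not given in the sources used here, and the p-values measure only the spread between these 4 pools.

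The deposited matrices hold raw UMI counts (distinct RNA molecules) per gene and barcode, not normalized, for 32285 genes, plus counts of antibody tags. Per the file headers the matrices were written by Cell Ranger 6.0.0, whereas the submitters' processing notes name Cell Ranger 7.0 and Seurat 4.3.0 with the mouse build mm10. Which of them made which value is not given in the sources used here. A deposited table gives each barcode a quality call and a genotype, and the barcodes without a genotype were those that failed the quality call; the rules behind both are not given in the sources used here. In replicate 1, 7683 of 9322 barcodes (82.4%) passed, and in replicate 2, 10346 of 24787 (41.7%). The 18029 passing cells were used without a further filter. Gene coordinates were taken from the GENCODE annotation of the same build, which held 32158 of the gene identifiers (99.6%). No deposited cell type annotation or cell cycle call was used.

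Raw counts were summed over the cells of each replicate and genotype, which gave 4 pools. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, filterByExpr), with replicate as a block and genotype as the effect, two-sided, and Benjamini-Hochberg adjusted p-values of at most 0.05 were called. Fold changes are IkBKO over WT on the log2 scale with standard errors (SE), and levels are CPM (UMIs of a gene over 1e6 UMIs of the pool). The block was chosen because both genotypes of a replicate shared 1 library; over 14742 genes the deviations from the genotype means of pools with the same number correlated at 0.686 (0.65 without sex-linked genes). With 4 pools and the block, 1 residual degree of freedom remained per gene, and the spread was shared across genes by edgeR. The steps were tested on simulated counts: of genes changed 1.5-fold, 2-fold and 4-fold over all LSK cells, 63.1% of 65, 75.8% of 66 and 100% of 63 were called, with 0.24% of unchanged genes; in a simulation of the smallest class the shares were 37.9% of 66, 70.2% of 67 and 98.5% of 65, with 0.07%.

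A set of 26 gene lists, 7 of them markers of other cell types, was tested with camera (preset correlation) and fry from limma 3.58.1, with adjustment over the lists. The alternative with an estimated correlation rests on 1 residual degree of freedom. A list that did not pass under it is therefore not shown to be explained by correlation between genes. They covered the IκB and NF-κB family, NF-κB target genes, interferon-stimulated genes, antigen presentation, inflammatory and growth factor receptors, HSC identity, HSC ageing, myeloid priming, lymphoid priming, megakaryocyte and erythroid priming, G1/S and G2/M cell cycle genes, quiescence, immediate-early genes, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, sex-linked genes, and mature neutrophils, B cells, T and NK cells, erythroid cells, mast cells and basophils, monocytes and dendritic cells, and stroma. Lists share members: 8 of the 14 IκB and NF-κB family genes are also in another list, as are 4 of the 16 HSC identity and 4 of the 22 HSC ageing genes, whereas the 7 lists of other cell types share none. The tests, lists, marker genes and alternatives were fixed before the data were examined, as was the rule for named genes: over all LSK cells the 12 highest and 12 lowest fold changes among called genes that moved the same way in both replicates with a mean of at least 10 CPM in 1 genotype, the 5 highest and 5 lowest per class, the IκB and NF-κB family, the sex-linked genes, and up to 4 members per list with the smallest p. Unnamed gene models were counted but not named by this rule.

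Cell classes were rebuilt from the counts with scanpy 1.11.5 and leidenalg 0.10.2: 2000 variable genes scaled within each library, cell cycle scores regressed out, 30 principal components, 15 neighbours and a resolution of 1.0, which gave 22 clusters. A cluster was named after the marker list with the highest mean log2 enrichment where this was at least 0.5 with at least 3 detected markers. These thresholds were set after the data were seen, and clusters below them stayed unnamed. Clusters past them also stayed unnamed where their leading genes held more markers of another list than of their own. In the first clustering this held for a cluster of 249 and 259 IkBKO against 59 and 11 WT cells, whose best name was dendritic/monocyte-like. Because 745 of the 2000 variable genes were called between genotypes, the shares of classes are given first from a clustering without the called genes (19 clusters). Gene tests within classes used the first clustering and classes with at least 50 cells in every pool. Numbers of cells per class were tested with edgeR (total cells as library size). The interaction of genotype and class was tested against the HSC-like class with pool as the block. Cell cycle phases were scored after thinning each cell to 5000 UMIs, which left out shallower cells. The doublet caller scrublet has not worked on these libraries: it called 1 cell in replicate 1 and 0 in replicate 2, so an alternative left out the 6% of cells with the highest scores.

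The alternatives were RLE scaling, DESeq2 1.42.0, no block, no filter on low counts or a mean of at least 10 CPM, leaving out mitochondrial, ribosomal and haemoglobin genes, a stricter cell filter (at least 1000 UMIs and 500 genes, at most 10% mitochondrial UMIs), thinning pools to one total, an estimated correlation for camera, other cluster resolutions, and leaving out each pool or replicate. Leaving out a pool required a fit without the block, in which the lone pool of a genotype was assumed to vary like the others. Alternatives chosen after seeing the data were the top doublet scores, a clustering scaled within pools, class tests with the clustering without called genes, classes of at least 20 cells, leaving out the mature and other-lineage classes, and re-weighting the pools to one class composition. The re-weighting rests on few WT cells in some classes. No test of differences between classes within WT was made, because the classes were rebuilt from the same counts. The values of 3 genes are not reported here.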

Results

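The question behind the libraries is whether altered IκB control of NF-κB turns blood-forming cells of mice towards the myeloid lineage, in stem cells and in their progeny. RNA of single LSK cells (lineage-negative, Sca-1-positive, Kit-positive marrow cells, the gate that holds stem cells and early progenitors) was counted in 2 libraries. Each library held wild-type (WT) and IκB-deficient (IkBKO) cells, told apart by antibody tags. Replicate 1 held 3721 WT and 3962 IkBKO LSK cells with 43674115 and 62834572 UMIs. Replicate 2 held 4963 WT and 5383 IkBKO cells with 42165571 and 61278938 UMIs. The median UMIs per cell were 9963 in WT and 13709 in IkBKO cells of replicate 1, and 6983 and 9641 in replicate 2. IkBKO cells thus carried more UMIs in both libraries. Xist, the RNA that coats the inactive X chromosome, stood at 1758 CPM in WT and 1267 CPM in IkBKO cells of replicate 1 and at 0.12 and 0.18 CPM in replicate 2. The Y-linked Ddx3y was absent from replicate 1 and stood at 50.3 and 52.1 CPM in replicate 2. The pairs of pools compared within a library were thus alike in these genes.

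The IκB proteins hold NF-κB dimers in the cytoplasm. Nfkbie, which encodes IκBε (ENSMUSG00000023947, mm10 chromosome 17, 45555703 to 45563169), fell from 9.11 and 12.1 CPM in WT to 2.04 and 1.97 CPM in IkBKO cells of replicates 1 and 2 (log2 fold change −2.29 ± 0.18 SE, edgeR adjusted p = 0.0028). Nfkbib, which encodes IκBβ (ENSMUSG00000030595, chromosome 7, 28758251 to 28767512), fell from 19.2 and 16.1 CPM to 6.64 and 7.93 CPM (−1.19 ± 0.13, adjusted p = 0.0073). Nfkbia, which encodes IκBα (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647), was at 47.7 and 76.0 CPM in WT and 42.6 and 59.7 CPM in IkBKO cells, a difference that did not pass (−0.17 ± 0.09, adjusted p = 0.25). The counts come from the 3′ ends of transcripts, so a tag outside a deleted part checks nothing. The deleted parts are not given in the sources used here. Of the 14 IκB and NF-κB family genes, 3 were higher and 4 lower (4 and 4 adjusted over the list alone). The list as a whole did not pass (camera adjusted p = 0.47). Bcl3 rose by 1.08 ± 0.10 log2 units, Relb by 0.92 ± 0.14 and Nfkb2 by 0.65 ± 0.13. Nfkbiz (−0.71 ± 0.11) and Nfkbid (−0.55 ± 0.13) fell. The other members had values between −0.17 for Rel and 0.23 for Nfkb1 and did not pass. Calls were then tested in pools without the mature and other-lineage classes and in pools re-weighted to one class composition (described below). In both Bcl3 (0.92 and 1.10), Nfkbie and Nfkbib stayed called. Relb (0.50 and 0.89; adjusted p = 0.15 and 0.11), Nfkb2 (0.45 and 0.53; adjusted p = 0.15 and 0.20) and Nfkbid (−0.50 and −0.59; adjusted p = 0.091 and 0.066) passed in neither, and Nfkbiz did not pass after re-weighting (−0.30, adjusted p = 0.26).

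The first comparison asked which genes differed between IkBKO and WT cells over the whole LSK gate. Many myeloid genes were higher in IkBKO cells, with 13 of 20 myeloid priming genes called and 7 not. Mpo, the granule myeloperoxidase, rose from 892 and 193 CPM to 2964 and 698 CPM (log2 1.89 ± 0.06, adjusted p = 4.3e-04). Csf1r, the receptor for macrophage colony-stimulating factor, rose by 1.76 ± 0.10. Genes of the MHC class II pathway, which presents peptides to T cells, were higher as well. Cd74 rose from 113 and 116 CPM to 420 and 698 CPM (2.33 ± 0.17) and H2-Eb1 from 47.5 and 43.2 CPM to 198 and 286 CPM (2.48 ± 0.16). In pools re-weighted to one class composition Cd74 was at 0.74 and H2-Eb1 at 0.82 (adjusted p = 0.53 for both) and Csf1r at 0.58 (adjusted p = 0.59), so these calls were lost, whereas Mpo was at 0.63 (adjusted p = 0.0057). Fos, a subunit of the AP-1 transcription factor, fell from 78.1 and 108.5 CPM to 12.8 and 16.8 CPM (−2.56 ± 0.08). Hlf, a transcription factor of stem cells, fell from 200.2 and 474 CPM to 52.9 and 212 CPM (−1.45 ± 0.18). Calprotectin genes of mature neutrophils were also lower. S100a9 fell from 461 and 426 CPM to 48.9 and 71.8 CPM (−2.81 ± 0.17). Of the WT UMIs of the mature neutrophil list 93.5% and 97.1% lay in the 29 and 16 neutrophil-like cells of replicates 1 and 2, and without the mature and other-lineage classes S100a9 was at −0.61 (adjusted p = 0.019).

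Of 14742 genes tested, 1051 were higher and 913 lower in IkBKO cells. Of the named genes the largest rise was that of AA465934, a processed transcript (ENSMUSG00000093483, chromosome 11, 83291699 to 83294632), from 5.24 and 4.55 CPM to 182.5 and 116.5 CPM (5.0 ± 0.15, adjusted p = 4.7e-04). In pools re-weighted to one class composition its log2 fold change was 4.53 (adjusted p = 0.17). Gdpd3, a lysophospholipase D (ENSMUSG00000030703, chromosome 7, 126766334 to 126775649), rose from 3.57 and 1.3 CPM to 51.4 and 36.7 CPM (4.33 ± 0.22, adjusted p = 0.0033). The next were the serpin Serpina3f (2.82 ± 0.30), the endosomal Ehd3 (2.80 ± 0.13), the oxysterol receptor Gpr183 (2.62 ± 0.23), the lysosomal reductase Ifi30 (2.49 ± 0.13), the metallothionein Mt1 (2.33 ± 0.13), H2-DMb2 (2.27 ± 0.17), H2-Aa (2.21 ± 0.18) and Igsf6 (2.18 ± 0.10). After re-weighting Ifi30 was at 0.58, Mt1 at 0.49, H2-Aa at 0.61 and Igsf6 at 0.44 (adjusted p = 0.72, 0.21, 0.54 and 0.71), and without the mature and other-lineage classes H2-DMb2 was at 0.31 (adjusted p = 0.37). Of the named genes the largest fall was that of Mid1, an X-linked ubiquitin ligase gene at the border of the pseudoautosomal region (ENSMUSG00000035299, chromosome X, 169685199 to 170005736), from 12.4 and 7.73 CPM to 0.16 and 0.60 CPM (−4.63 ± 0.64, adjusted p = 0.035). Copies of this region are near-identical, which makes its counts uncertain. Wfdc18 (−3.24 ± 0.16), the antimicrobial peptide gene Camp (−2.94 ± 0.15), Ddx4 (−2.88 ± 0.14), Wfdc17 (−2.76 ± 0.08), S100a8 (−2.43 ± 0.09), Paqr5 (−2.33 ± 0.28), Tanc1 (−2.33 ± 0.16) and Fosb (−2.29 ± 0.18) followed. Without the mature and other-lineage classes Camp was at −0.17 and S100a8 at 0.021 (adjusted p = 0.59 and 0.91). Without the replicate block edgeR called 0 genes (1410 at an unadjusted p under 0.05, against 4865 with it). DESeq2 with the block called 963 higher and 601 lower, 1259 of them shared with the edgeR calls. Leaving out 1 pool, which also removes the block, left 53 higher and 43 lower genes without WT replicate 1 and 33 and 33 without IkBKO replicate 1. It left 9 and 16 without WT replicate 2, and 59 and 77 without IkBKO replicate 2.

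**Figure D1:**
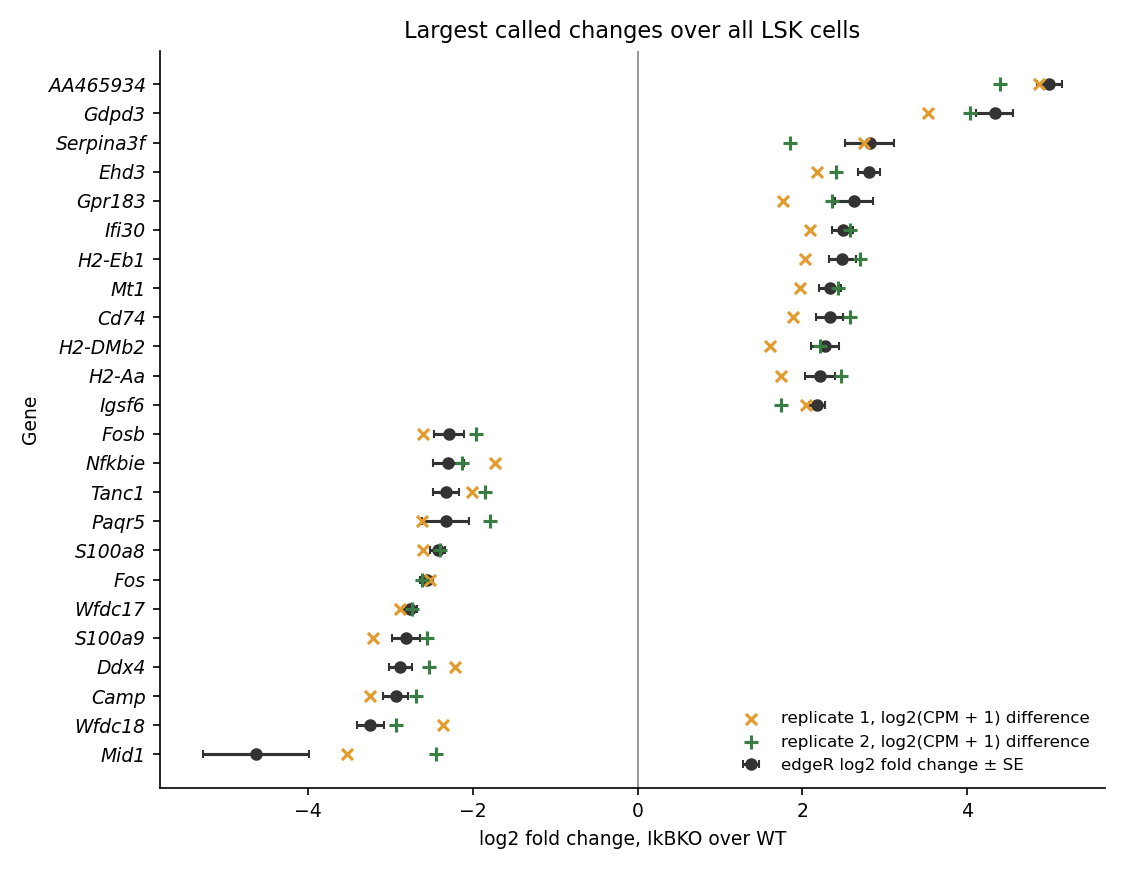
Log2 fold change, IkBKO over WT, of the 12 highest and 12 lowest named genes over all LSK cells. Circles with bars are edgeR estimates ± SE over 4 pools, and crosses and plus signs are differences of log2(CPM + 1) within replicate 1 and replicate 2; the estimates run from −4.63 for Mid1 to 5.0 for AA465934.

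Because IkBKO and WT pools held different mixtures of cells, the same test was run on pools without the mature and other-lineage classes, and on pools re-weighted to one class composition, both chosen after seeing the data. Without those classes 550 genes were higher and 469 lower, of which 962 were shared with the first test. After re-weighting 216 were higher and 229 lower, of which 373 were shared. Besides the genes whose values are given beside them, Prtn3 (0.31), Ms4a6c (0.53), Mcpt8 (0.41), Procr (−0.43), Notch1 (−0.27), Nupr1 (0.76), Rrm2 (0.078), Atp5g1 (0.13), Ifit1 (−0.69) and Tsix (−0.31) no longer passed after re-weighting. S100a9 (−2.43), Camp (−2.50), S100a8 (−2.05), Mid1 (−4.63, adjusted p = 0.052), Ifi27l2a (−1.38), Ccr9 (−1.73) and Hba-a1 (−3.46) did not pass either, although their fold changes stayed about as large or grew. Genes that still passed at values more than 1.5-fold smaller were Gpr183 (1.08), Gdpd3 (3.54), Wfdc18 (−2.37), Wfdc17 (−2.16), Ddx4 (−2.1), Paqr5 (−1.69), Hlf (−0.79), Ifi44 (−0.84) and Flt3 (−0.42), and Slc4a1 had a larger one (−3.87). Without the mature and other-lineage classes Gpr183 (1.69) and Ifi30 (1.74) were smaller and Igll1 (2.45) and Ccr9 (−3.38) larger.

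Myeloid and antigen presentation genes made up the clearest rising groups. Of 20 myeloid priming genes, 13 rose, 0 fell and 7 did not pass (15 and 0 adjusted over the list alone; camera adjusted p = 1.5e-27, median log2 1.24). Prtn3, the neutrophil serine protease, rose by 1.27 ± 0.09 and Igsf6 by 2.18 ± 0.10. With an estimated correlation the adjusted p was 0.48. After re-weighting to one class composition the myeloid list had an adjusted p = 0.28. Of 14 antigen presentation genes, 11 rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 7.5e-19). They included Ciita, the master regulator of MHC class II (2.07 ± 0.18; 0.82 without the mature and other-lineage classes and 0.86 after re-weighting, adjusted p = 0.062 and 0.12), and the class I gene H2-Q7 (0.92 ± 0.08). This list had an adjusted p = 0.48 with an estimated correlation and an adjusted p = 1.7e-10 after re-weighting. Markers of other cell types moved with both groups. Of 9 monocyte and dendritic cell genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 2.2e-12, and adjusted p = 0.48 with an estimated correlation), such as Ms4a6c (1.74 ± 0.09). Of 8 mast cell and basophil genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 6.2e-07, and adjusted p = 0.59 with an estimated correlation), such as Mcpt8 (1.51 ± 0.10). After re-weighting the monocyte and dendritic cell list and the mast cell and basophil list no longer passed (adjusted p = 0.33 and 0.091).

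NF-κB target genes and receptors moved in both directions. Of 41 NF-κB target genes 15 rose and 6 fell (20 and 6 adjusted over the list alone; camera adjusted p = 7.4e-04, and adjusted p = 0.48 with an estimated correlation). Tnfaip2 rose by 1.15 ± 0.08 and the anti-apoptotic Bcl2a1d by 2.87 ± 0.23, whereas the chemokine gene Ccl3 fell (−1.60 ± 0.13). After re-weighting Tnfaip2 was at −0.058 (adjusted p = 0.75). Bcl2a1d was at 1.10 after re-weighting and at 1.25 without the mature and other-lineage classes (adjusted p = 0.23 and 0.13). Without the mature and other-lineage classes the NF-κB target list had an adjusted p = 0.75, and after re-weighting an adjusted p = 0.0011 (higher). Among 32 interferon-stimulated genes 8 rose and 7 fell (13 and 12 adjusted over the list alone), the list did not pass (adjusted p = 0.84), and its median log2 fold change of 0.10 and mean of −0.03 differed in sign. By camera the interferon list was higher after re-weighting (adjusted p = 7.6e-05) but not without the mature and other-lineage classes (adjusted p = 0.99). Gbp3 rose (1.48 ± 0.10), whereas Ifi27l2a (−1.37 ± 0.08), Ifi44 (−1.47 ± 0.10) and Ifit1 (−1.15 ± 0.15) fell. Of 20 inflammatory and growth factor receptors 6 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.057). The cytokine receptor subunits Csf2rb (1.07 ± 0.09) and Il6st (1.05 ± 0.08) rose and Flt3 fell (−1.01 ± 0.08).

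Some stem cell and lymphoid genes were lower over the LSK gate. Of 16 HSC identity genes 7 fell and 0 rose (8 and 1 adjusted over the list alone; camera adjusted p = 1.2e-07, and adjusted p = 0.59 with an estimated correlation). They included the surface receptor Procr (−1.02 ± 0.09), Gcnt2 (−1.32 ± 0.10) and Hoxa9 (−0.85 ± 0.08). Of 16 lymphoid priming genes 5 fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 2.4e-08, and adjusted p = 0.59 with an estimated correlation). The chromatin organiser Satb1 was at −1.18 ± 0.08, Notch1 at −0.78 ± 0.08 and the chemokine receptor Ccr9 at −1.87 ± 0.19. Of 21 HSC ageing genes, which are higher in stem cells of old animals, 7 rose and 3 fell (11 and 5 adjusted over the list alone; adjusted p = 9.0e-07, and adjusted p = 0.59 with an estimated correlation). Nupr1 was at 1.27 ± 0.17 beside Ehd3 and Mt1. Of 18 megakaryocyte and erythroid priming genes 1 rose and 2 fell (2 and 2 adjusted over the list alone), while the median of the list was 0.48 (adjusted p = 0.012, and adjusted p = 0.73 with an estimated correlation). The transferrin receptor gene Tfrc rose (0.95 ± 0.09). After re-weighting, the HSC identity, lymphoid, ageing, and megakaryocyte and erythroid lists had adjusted p = 0.0018, 0.014, 0.0087 and 0.28.

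Many cell cycle and respiratory genes were higher in IkBKO cells and most immediate-early genes were lower. Of 30 G1/S genes 11 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 5.1e-07), such as Rrm2 (0.67 ± 0.07). Of 42 G2/M genes 25 rose and 1 fell (38 and 1 adjusted over the list alone; adjusted p = 5.6e-16), such as the cyclin gene Ccnb1 (0.80 ± 0.09). Both lists had an adjusted p = 0.48 with an estimated correlation. Of 14 quiescence genes 2 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.59 with an estimated correlation), namely Btg2 (−1.19 ± 0.08) and Egr1 (−1.60 ± 0.12). Of 15 immediate-early genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 6.4e-29, and adjusted p = 0.48 with an estimated correlation). Zfp36 was at −1.46 ± 0.10, Jun at −1.23 ± 0.09 and Jund at −1.09 ± 0.08. This list is known to respond to cell handling. Of 90 oxidative phosphorylation genes 43 rose and 0 fell (70 and 0 adjusted over the list alone; adjusted p = 1.1e-16, and adjusted p = 0.63 with an estimated correlation), most by small amounts such as Atp5g1 (0.53 ± 0.08). Of 82 ribosomal protein genes 15 rose and 1 fell (17 and 2 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.63 with an estimated correlation). Of 14 glycolysis genes 2 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.067). None of the 13 mitochondrially encoded genes passed (0 adjusted over the list alone; adjusted p = 0.78).

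Among the markers of other cell types, some mature neutrophil genes fell. Of 8 mature neutrophil genes 4 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 4.0e-24, and adjusted p = 0.48 with an estimated correlation). Of 7 erythroid genes 2 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.51 with an estimated correlation), namely the globin gene Hba-a1 (−1.45 ± 0.12) and Slc4a1 (−1.92 ± 0.35). The summed alpha and beta globin genes were at 120 CPM in WT and 59.0 CPM in IkBKO cells of replicate 1 and at 88.7 and 91.7 CPM in replicate 2, so globin RNA did not fall in both replicates. Without the mature and other-lineage classes both lists had an adjusted p = 0.75, and after re-weighting they had adjusted p = 5.7e-28 and 8.6e-15. Of 9 B cell genes 1 rose (Igll1, 1.00 ± 0.18; 1 adjusted over the list alone; list adjusted p = 0.75). Of 8 T and NK cell genes 1 fell (Trbc2, −1.52 ± 0.21; 1 adjusted over the list alone; adjusted p = 0.13). Of 4 detected stroma genes 0 passed (0 adjusted over the list alone; adjusted p = 0.44). Of 6 sex-linked genes 1 fell (Tsix, −0.63 ± 0.12; 1 adjusted over the list alone; adjusted p = 0.42). Tsix overlaps Xist on the other strand and was chiefly detected in replicate 1. Of the 26 lists, 11 were higher and 6 lower by camera. With camera 0 passed with an estimated correlation, and 0 passed by fry after adjustment (6 before it, lowest adjusted p = 0.17). The correlation was estimated with 1 residual degree of freedom. It was −0.055 for antigen presentation, below the preset one, and 1 for mast cell and basophil genes, yet neither list passed. This alternative thus cannot tell whether correlation between genes lies behind the list results.

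**Figure D2:**
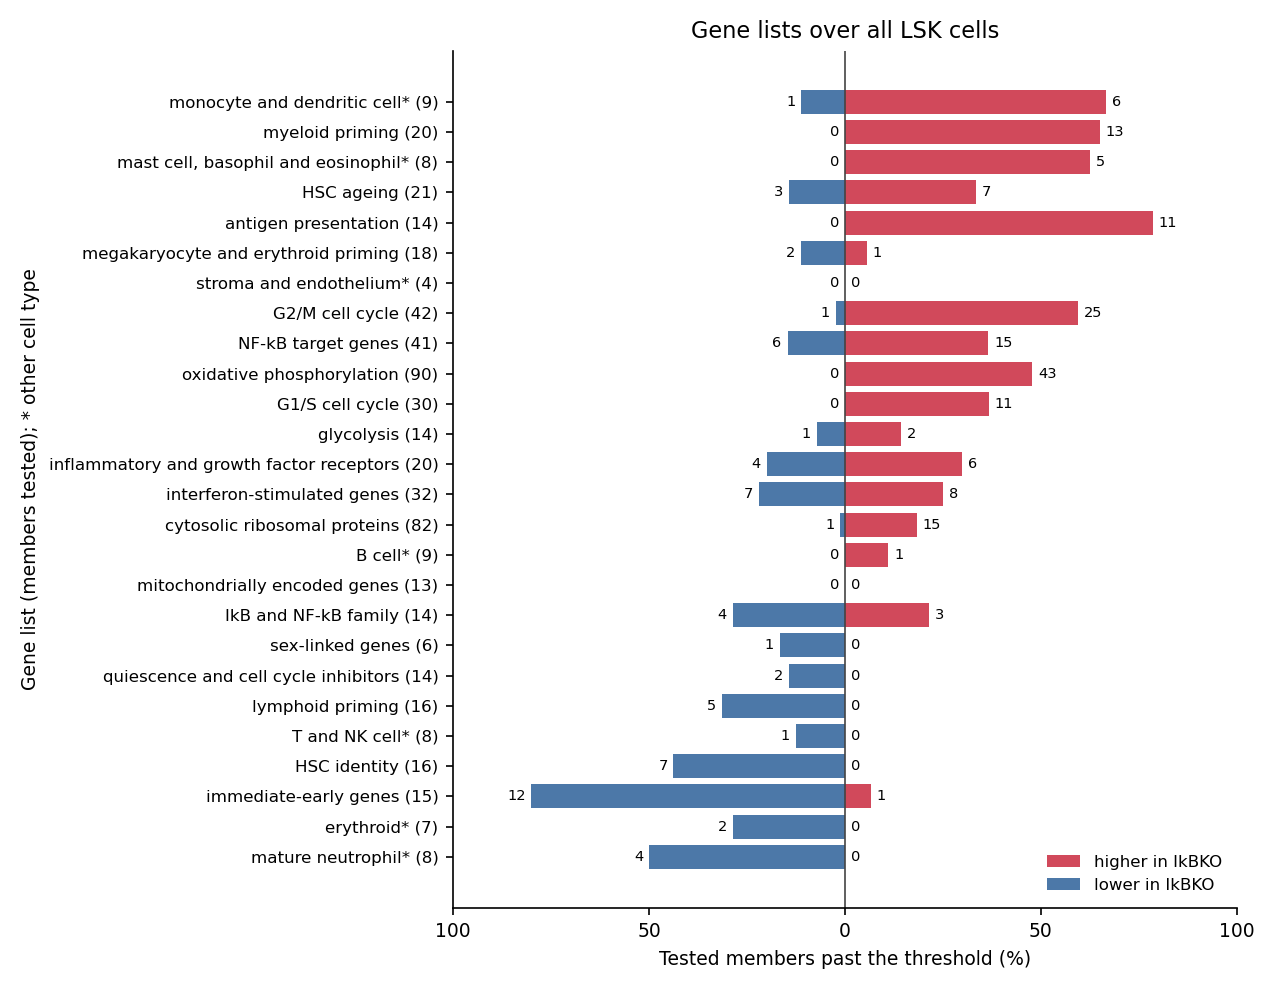
Percent of the tested members of each gene list that were higher (right, red) or lower (left, blue) in IkBKO over all LSK cells, with the number of genes at each bar. Of the myeloid priming genes 13 of 20 were higher, and of the immediate-early genes 12 of 15 were lower.

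The second comparison asked how the makeup of the LSK gate differed. Myeloid-like cells made up 2.71% of WT and 19.2% of IkBKO cells in replicate 1 and 0.52% and 2.42% in replicate 2. Their ratio was 5.76 (edgeR adjusted p = 0.016). Their cluster was led by Ly6c2, F13a1 and Hp, with Elane and Mpo also among its leading genes. In the first clustering the myeloid-like class also held a cluster led by Ctsg and Mpo. Erythroid-like cells rose from 2.31% to 9.92% and from 0.28% to 4.74% (ratio 8.01, adjusted p = 0.016). This ratio depended on the clustering: at resolution 1.5 erythroid-like cells went from 1.13% to 1.41% and from 1.09% to 2.34% (ratio 1.66, adjusted p = 0.18). There 523 of the 748 cells (69.9%) were named megakaryocyte/erythroid-like instead, most of them in a cluster led by Gm15915 and Car1 (365 and 161 IkBKO against 47 and 5 WT cells). In the first clustering the summed globin genes of erythroid-like cells went from 2893 to 392 CPM and from 1894 to 110 CPM. The class thus held cells of unlike globin content in the 2 genotypes, on 75 and 12 WT cells. Dendritic/monocyte-like cells rose from 2.20% to 6.01% and from 0.52% to 7.88% (ratio 6.21, adjusted p = 0.016), but at resolutions 0.5 and 1.5 the ratios of 5.85 and 6.35 did not pass (adjusted p = 0.12 and 0.18). The myeloid-like ratios there were 5.99 and 7.10 (adjusted p = 0.063 and 2.0e-04). Lymphoid-like cells, with Dntt and Il7r among their leading genes, were at 13.1% and 5.28% in replicate 1 and at 13.8% and 6.37% in replicate 2. Their ratio of 0.43 did not pass (adjusted p = 0.17). These shares come from the clustering without called genes. Megakaryocyte/erythroid-like cells were at 5.48% and 8.48%, then 2.92% and 8.42% (ratio 2.11, adjusted p = 0.21). HSC-like cells were at 19.5% and 13.7%, then 15.7% and 21.0% (ratio 0.97, adjusted p = 0.94), so that in this clustering the HSC-like share moved in opposite directions in the replicates.

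Of the smaller classes, mast/basophil-like cells had a ratio of 2.88 (adjusted p = 0.14), neutrophil-like cells 2.68 (adjusted p = 0.14), T/NK-like cells 0.47 (adjusted p = 0.22) and B-like cells 0.89 (adjusted p = 0.91). Clusters that stayed unnamed held 48.5% of WT and 29.2% of IkBKO cells in replicate 1 and 64.4% and 45.7% in replicate 2. The first clustering, which used the called genes, gave ratios of 6.40 for myeloid-like, 9.02 for erythroid-like, 5.85 for dendritic/monocyte-like and 0.41 for lymphoid-like cells (adjusted p = 0.085, 0.085, 0.12 and 0.085). It gave a lower HSC-like share in both replicates (31.3% and 14.7%, then 31.4% and 22.4%; ratio 0.58, adjusted p = 0.19). The same held at resolution 0.5 (55.3% and 13.1%, then 64.5% and 20.4%, ratio 0.27, adjusted p = 0.082). At resolution 1.5 the shares were 24.8% and 1.74%, then 19.4% and 2.27% (ratio 0.091, adjusted p = 7.4e-05). There, however, a cluster of 509 and 1052 IkBKO against 21 and 70 WT cells stayed unnamed. Its best name was HSC-like (mean log2 enrichment 1.15), so the ratio of 0.091 leaves these cells out. The HSC-like share is thus tied to the clustering and its naming. The unnamed clusters of the first clustering held 41.2% and 29.8%, then 51.9% and 43.7%. Without the block this clustering gave ratios of 5.36 for myeloid-like, 6.38 for erythroid-like and 5.29 for dendritic/monocyte-like cells (edgeR adjusted p = 0.23, 0.23 and 0.18). For the clustering without called genes no fit without the block was made. The cells were sorted on Sca-1 and Kit, so the shares are those of the gate. Ly6a, which encodes Sca-1, stood at 52.4 CPM in WT and 89.7 CPM in IkBKO cells of replicate 1 and at 90.3 and 117 CPM in replicate 2, and Kit at 199 and 118 CPM, then 272 and 194 CPM. In the first clustering IkBKO cells carried 1.08 and 1.12 times the UMIs of WT cells in the myeloid-like class and 1.31 and 1.78 times in the lymphoid-like class of replicates 1 and 2, against 1.38 and 1.38 over all cells.

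**Figure D3:**
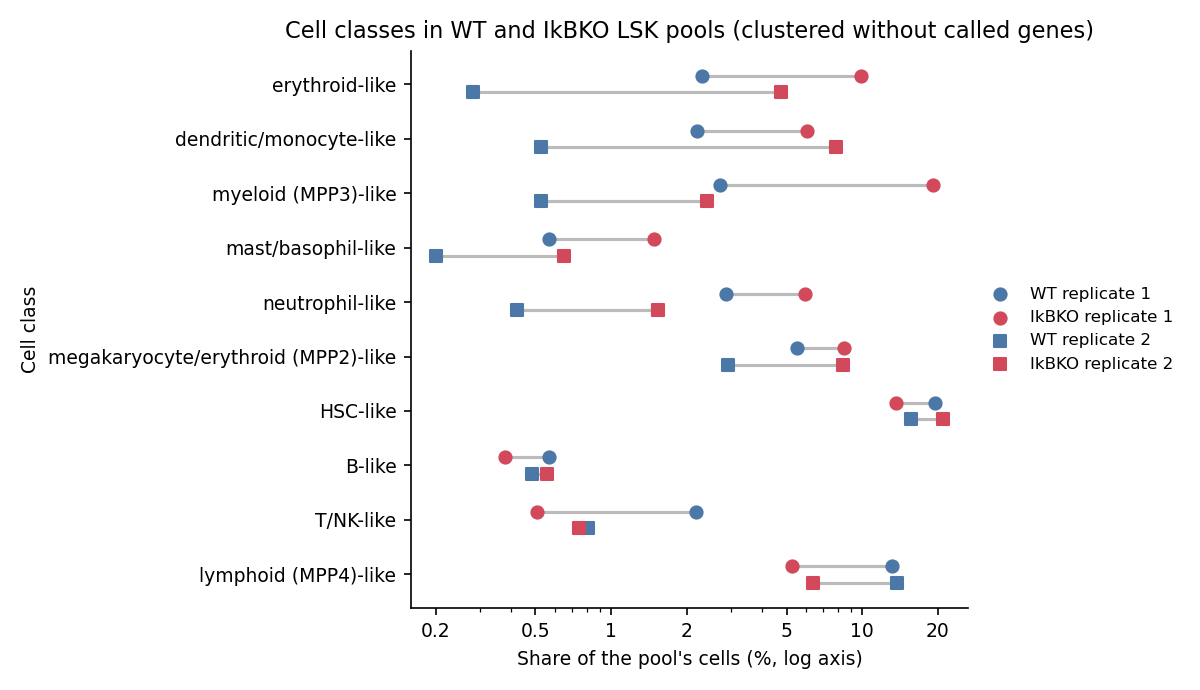
Share of cells per class, in percent on a log axis, for each pool, from the clustering without called genes. The myeloid-like share is 2.71% and 0.52% in the WT pools and 19.2% and 2.42% in the IkBKO pools of replicates 1 and 2.

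The third comparison asked whether the share of cells scored in S or G2/M differed. After thinning to 5000 UMIs, 66.2% of WT and 76.3% of IkBKO LSK cells in replicate 1 and 55.8% and 65.6% in replicate 2 were scored in these phases, a mean difference of 9.91 percentage points (edgeR adjusted p = 0.0065). In lymphoid-like cells the shares were 60.7% and 74.7%, then 49.3% and 77.8% (21.2 points, adjusted p = 0.017). HSC-like cells (60.3% and 58.7%, then 52.5% and 48.2%; −2.95 points, adjusted p = 0.32) and megakaryocyte/erythroid-like cells (−1.61 points, adjusted p = 0.74) did not pass. Thinning left out 6 WT and 1 IkBKO lymphoid-like cells in replicate 1 and 100 and 6 in replicate 2. Over all LSK cells it left out 188 WT and 102 IkBKO cells in replicate 1 and 956 and 503 in replicate 2. Without it the shares were 66.0% and 76.9%, then 49.6% and 63.5% (12.5 points, adjusted p = 0.078), and in lymphoid-like cells the difference of 24.4 points did not pass either (adjusted p = 0.078). With 2500 UMIs the differences of 13 points over all and 23.2 points in lymphoid-like cells had adjusted p = 0.097 and 0.35. Without the block the adjusted p over all cells was 0.31 and in lymphoid-like cells 0.075. The phase shares were not set to one class composition, so the difference over all cells may follow the class mixture. Myeloid-like cells, more frequent in IkBKO pools, were at 91.7% and 96.5%, then 93.8% and 86.8%. Unnamed cells were at 65.2% and 76.5%, then 56.1% and 63.6%. Free RNA enters such scores, and the scores alone do not show cycling.

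The fourth comparison asked which genes differed within cell classes, in classes with at least 50 cells in every pool. In HSC-like IkBKO cells many interferon and antigen presentation genes were higher. The interferon-induced GTPase gene Igtp rose by 2.03 ± 0.13 log2 units, and the MHC class II gene H2-Ab1 rose by 2.07 ± 0.10. Fos fell from 120.9 and 163 CPM to 15.1 and 21.8 CPM (−2.92 ± 0.11, adjusted p = 7.3e-14), and Satb1 from 125.5 and 123 CPM to 42.8 and 34.2 CPM (−1.68 ± 0.10). Pf4, a platelet chemokine gene, rose by 1.46 ± 0.11 and Gata1, an erythroid and megakaryocytic factor, by 1.60 ± 0.38. Of 12756 genes tested 654 were higher and 475 lower. By the rule the largest rises of named genes were those of Gdpd3 (5.58 ± 0.19), AA465934 (5.02 ± 0.12), Serpina3f (3.57 ± 0.33), the interferon-induced Gbp4 (3.14 ± 0.50) and Podnl1 (3.03 ± 0.25). The largest falls were those of Mid1 (−4.00 ± 0.40), Sema3d (−3.17 ± 0.29), Fos, Tmem121 (−2.51 ± 0.40) and Nfkbie (−2.37 ± 0.26).

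In the HSC-like class different clusters held the 2 genotypes. WT cells lay mostly in a cluster led by Fos, Fosb and Egr1 (965 and 951 WT cells against 24 and 16 IkBKO cells) and in a smaller one (177 and 528 against 27 and 119). IkBKO cells lay mostly in a cluster led by Iigp1 and Ly6a (532 and 1071 against 23 and 81 WT cells), so immediate-early and interferon genes lead the clusters themselves. The counts from the clustering without called genes are therefore given beside the first ones. These list p-values rest on the preset correlation of camera, and with an estimated one 0 lists passed (lowest adjusted p = 0.72). All 14 immediate-early genes fell (14 adjusted over the list alone; camera adjusted p = 4.8e-35; 14 of 14 in the clustering without called genes). Of 31 interferon genes 15 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 4.6e-17; 12 and 1 of 32). Of 14 antigen presentation genes 8 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 4.6e-17; 8 and 0 of 14). Of 14 lymphoid priming genes 5 fell (7 adjusted over the list alone; adjusted p = 9.9e-07; 1 higher and 5 lower of 12). Of 18 ageing genes 7 rose (8 higher and 2 lower adjusted over the list alone; adjusted p = 6.2e-05; 6 and 2 of 18), led by Ehd3 (2.38 ± 0.23) and Plscr2 (3.02 ± 0.35). Of 17 megakaryocyte and erythroid priming genes 5 rose (5 adjusted over the list alone; adjusted p = 5.0e-04; 4 and 1 of 17). Of 30 G1/S genes 7 rose (14 adjusted over the list alone; adjusted p = 3.3e-05; 6 and 0 of 30). Of 13 mitochondrially encoded genes 5 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.011; 8 lower of 13). Of 32 NF-κB target genes 8 rose and 3 fell (12 and 4 adjusted over the list alone; adjusted p = 0.011; 4 and 3 of 31). Others had more calls in the other clustering: G2/M genes went from 6 higher and 2 lower (6 and 2 adjusted over the list alone) to 14 and 1 of 42, oxidative phosphorylation genes from 4 and 1 of 90 (4 and 1) to 17 and 0 of 89, and ribosomal protein genes from 10 and 2 (14 and 3) to 31 and 1 of 80. HSC identity genes differed between the clusterings, with 7 of 16 higher and 3 lower in the first (7 and 3 adjusted over the list alone; adjusted p = 0.14) and 1 higher and 5 lower in the other. Hlf fell in the first by 0.43 ± 0.07 log2 units. Of 19 myeloid priming genes 1 rose and 1 fell (2 and 2 adjusted over the list alone; adjusted p = 0.50), the fall being that of Cebpa (−0.87 ± 0.16; 0.24 in the other direction with clustering scaled within pools, adjusted p = 0.36), against 5 higher and 0 lower of 18 in the clustering without called genes. DESeq2 called 170 higher and 104 lower genes, and edgeR without the block 43 and 25. Leaving out 1 pool left 45 and 43 (WT replicate 1), 36 and 29 (IkBKO replicate 1), 66 and 42 (WT replicate 2) or 38 and 13 (IkBKO replicate 2). The clustering without called genes gave 621 and 414, of which 713 were shared with the first.

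In lymphoid-like IkBKO cells many cell cycle and some respiratory genes were higher, and some stem cell genes were lower. With an estimated correlation in camera, however, 0 lists passed in this class, with an adjusted p = 0.66 for G1/S, 0.68 for oxidative phosphorylation and 0.64 for G2/M, HSC identity, immediate-early, myeloid priming and B cell genes. Of 30 G1/S genes 18 rose and 0 fell (24 and 0 adjusted over the list alone; adjusted p = 1.0e-14), such as Uhrf1 (0.83 ± 0.14). Of 42 G2/M genes 19 rose and 0 fell (27 and 1 adjusted over the list alone; adjusted p = 1.7e-11), such as Cdca3 (0.83 ± 0.15). Hlf fell from 51.0 and 159 CPM to 14.9 and 37.8 CPM (−1.90 ± 0.16, adjusted p = 5.3e-14) among 5 of 9 HSC identity genes that fell (5 adjusted over the list alone; adjusted p = 8.4e-12). Fos fell by 3.06 ± 0.18 log2 units among 10 of 14 immediate-early genes (10 adjusted over the list alone; adjusted p = 8.6e-29). Of 89 oxidative phosphorylation genes 18 rose and 0 fell (43 and 0 adjusted over the list alone; adjusted p = 1.4e-13). Of 15 myeloid priming genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.014), including the granule protease gene Ctsg (1.89 ± 0.15). Of 30 interferon genes 5 rose and 7 fell (7 and 9 adjusted over the list alone; adjusted p = 0.58), with Ly6e at 1.41 ± 0.14 and Ifi44 at −2.03 ± 0.27. None of the 16 lymphoid priming genes passed (0 adjusted over the list alone; adjusted p = 0.35).

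B cell genes were higher in the same lymphoid-like cells, with 4 of 5 tested genes rising (4 adjusted over the list alone; camera adjusted p = 2.8e-07, and 0.64 with an estimated correlation), including Cd79a, a subunit of the B cell receptor (3.27 ± 0.28). Of 10638 genes tested 504 were higher and 464 lower. AA465934 (4.89 ± 0.18) and Gdpd3 (4.41 ± 0.30) rose, and Tmem158 (−4.02 ± 0.26) fell. Synpo2 had 2 UMIs in WT and 68 in IkBKO cells, a CPM ratio of 52.0 (95% exact interval 13.9 to 438). Calm4 had 110 and 1, a ratio of 71.9 in the other direction (12.6 to 2860), and Ddit4l had 140 and 3, a ratio of 30.5 (10.2 to 150). Mid1 had 92 UMIs in WT and 0 in IkBKO cells, at least 20-fold lower against a floor of 3 counts over the group. Such intervals and floors cover counting error only. At resolution 1.5 a lymphoid-like cluster had Tmem158, Ddit4l and Calm4 among its leading genes. It held 86 and 198 WT but 3 and 0 IkBKO cells of replicates 1 and 2. The falls of these genes may thus also compare different cells. In the clustering without called genes 14 G1/S genes were higher and 7 G2/M genes higher and 1 lower. Of 4 B cell genes 1 was higher, and 9 of 17 myeloid priming genes were higher and 1 lower. It called 398 higher and 425 lower genes, of which 663 were shared. Beside 504 and 464, DESeq2 called 51 and 40 and edgeR without the block 116 and 159. Pools thinned to one total gave 192 and 210, clustering scaled within pools gave 106 and 145, a mean of at least 10 CPM gave 304 and 323. Leaving out WT replicate 1, IkBKO replicate 1, WT replicate 2 or IkBKO replicate 2 gave 130 and 215, 84 and 99, 64 and 94, or 119 and 125.

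In megakaryocyte/erythroid-like IkBKO cells many antigen presentation and interferon genes were higher, although with an estimated correlation in camera 0 lists passed (lowest adjusted p = 0.59). H2-Eb1 rose from 2.93 and 2.52 CPM to 98.8 and 33.5 CPM (4.76 ± 0.26, adjusted p = 3.8e-68) among 11 of 14 antigen presentation genes that rose (12 adjusted over the list alone; adjusted p = 1.7e-59). The GTPase gene Iigp1 rose by 2.79 ± 0.21 among 15 of 29 interferon genes (15 higher and 1 lower adjusted over the list alone; adjusted p = 2.9e-25). Of 13 immediate-early genes 7 fell (10 adjusted over the list alone; adjusted p = 1.8e-25). Of 88 oxidative phosphorylation genes 13 rose (32 adjusted over the list alone; adjusted p = 1.8e-14). Of 80 ribosomal protein genes 15 rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 3.7e-05). Of 17 ageing genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 5.9e-09). Of 12 lymphoid priming genes 3 fell (4 adjusted over the list alone; adjusted p = 1.1e-04), among them Dntt (−2.63 ± 0.52). G1/S genes (1 higher of 30, 1 adjusted over the list alone; adjusted p = 0.71) and G2/M genes (2 lower of 42, 2 adjusted over the list alone; adjusted p = 0.051) did not pass as lists. Of 14 myeloid genes 1 rose, Plac8 (1.00 ± 0.07; 1 adjusted over the list alone; adjusted p = 0.066). Of 10626 genes tested 208 were higher and 144 lower. Gdpd3 (5.12 ± 0.40), AA465934 (4.86 ± 0.19), Serpina3f (3.59 ± 0.40) and H2-Aa (3.20 ± 0.25) were highest beside H2-Eb1. Tanc1 (−2.46 ± 0.37), Fos (−2.31 ± 0.20), Wfdc17 (−1.96 ± 0.38), the pseudogene Olfr1369-ps1 (−1.72 ± 0.39) and Fosb (−1.57 ± 0.17) were lowest. DESeq2 called 23 and 3 genes, edgeR without the block 18 and 11, pools thinned to one total gave 134 and 66 and clustering scaled within pools 450 and 345. Leaving out WT replicate 1 or WT replicate 2 gave 1 and 0 genes, and leaving out IkBKO replicate 1 or 2 gave 36 and 36 or 88 and 47.

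**Figure D4:**
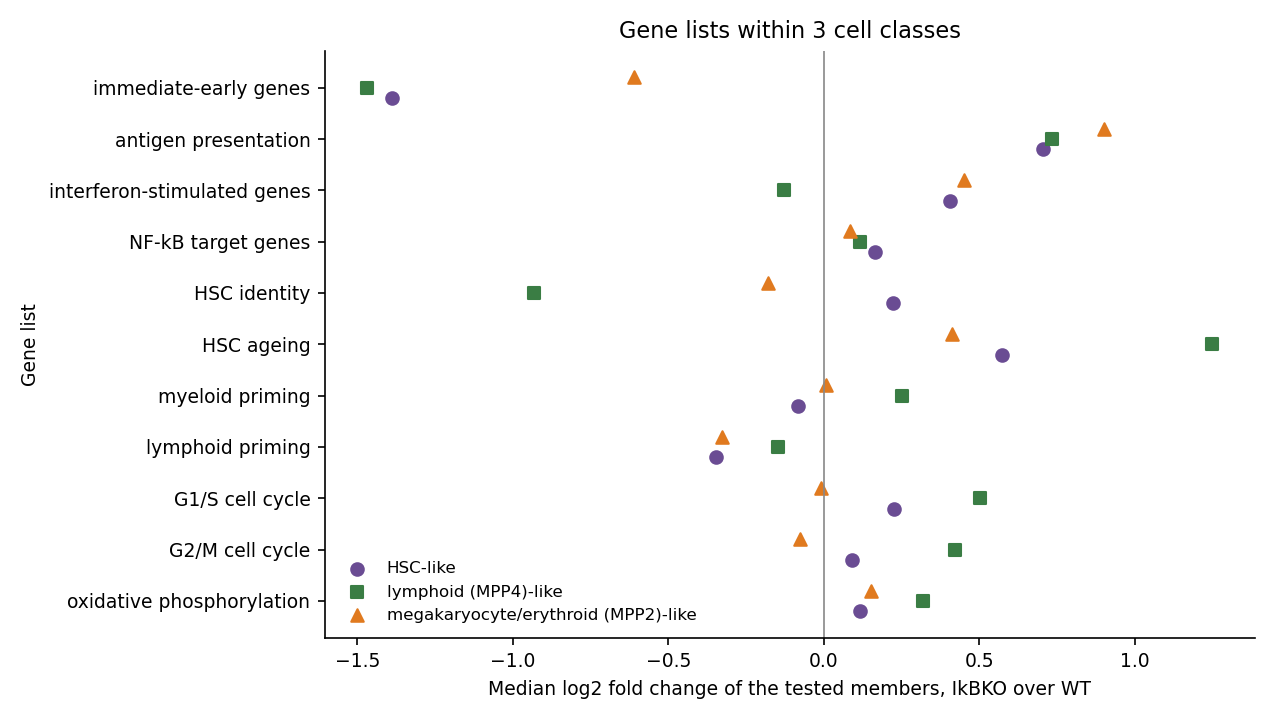
Median log2 fold change, IkBKO over WT, of gene lists (symbols) in the HSC-like, lymphoid-like and megakaryocyte/erythroid-like classes. The interferon medians are 0.40, −0.13 and 0.45 and the G1/S medians are 0.23, 0.50 and −0.01 in that order.

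The calls of the classes overlapped. HSC-like and lymphoid-like cells shared 139 higher and 148 lower genes, against 21.5 and 18.6 for independent lists of the same sizes. HSC-like and megakaryocyte/erythroid-like cells shared 110 and 76 (10.0 and 5.2), and lymphoid-like and megakaryocyte/erythroid-like cells 73 and 58 (8.3 and 5.1). The classes come from the same pools and are not independent. In the interaction test over 12022 genes, 123 genes had a larger and 151 a smaller fold change in lymphoid-like than in HSC-like cells (1921 at an unadjusted p under 0.05), and 3 had a larger and 2 a smaller fold change in megakaryocyte/erythroid-like cells (808 unadjusted). Without the pool block edgeR called 0 genes in either class (765 and 280 unadjusted), and DESeq2 was not run on this test. The genotypes of the HSC-like class lay mostly in different clusters, and the interaction was not refitted with the clustering without called genes. Differences of whole lists between classes were not tested.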

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

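The tests on neutrophil-like cells, on linked DNA and on the chromosome 11 segment were chosen after the results they address were seen, whereas those on the sort gate and on depth were written down before.

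Summed over all LSK cells, neutrophil transcripts were lower in IkBKO pools, with S100a9 at −2.81 ± 0.17 log2 units. Outside the neutrophil-like class, UMIs of the list per IkBKO cell were 1.31 and 3.33 times the WT value in replicates 1 and 2. In replicate 2, 2308 and 1437 of these 5294 UMIs lay in dendritic/monocyte-like and erythroid-like cells. The values were 0.686 and 0.729 times WT in HSC-like and 0.452 and 0.182 times in myeloid-like cells. Free RNA shared by both genotypes of a library is argued against, since at most 6.5% of the WT UMIs of this list lay outside the neutrophil-like class of either library. Fewer neutrophil-like cells in IkBKO pools are argued against as the whole cause, since the IkBKO share of this class was 1.61 times that of WT in replicate 2, where S100a9 was lower too; the class held 29 and 16 WT and 9 and 28 IkBKO cells in replicates 1 and 2. UMIs of the list per neutrophil-like cell were 0.362 and 0.088 times the WT value. A less mature state of these IkBKO cells may remain as a biological explanation and was not tested.

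Myeloid-like and erythroid-like shares of the LSK gate were larger in IkBKO pools, with ratios of 5.76 and 8.01, although the erythroid-like ratio was 1.66 at resolution 1.5 (adjusted p = 0.18), where 69.9% of these cells were named megakaryocyte/erythroid-like. The higher UMI depth of IkBKO cells is argued against as the whole cause, since after thinning every cell to one depth the share of cells with at least 5 Mpo or 5 Car1 UMIs was at least 3.06 times as high in IkBKO. Entry of Sca-1-low progenitors into the sort gate through higher Ly6a RNA stays open, since Ly6a CPM in myeloid-like cells was at least 2.35 times the WT value in both libraries. In erythroid-like cells the ratios were 17.8 and 1.31 in replicates 1 and 2, on 2 and 4 WT UMIs, so that this explanation cannot be told apart from others there. A true expansion of both lineages may equally lie behind the shares and was not tested, since no cells outside the gate were measured. In the first clustering erythroid-like IkBKO cells held less globin RNA than WT cells of that class, so its makeup may differ between the genotypes.

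Among 8384 tested genes with coordinates and a mean of at least 10 CPM in 1 genotype, 8 differed by 8-fold or more and were called, including AA465934, Gdpd3, Wfdc18 and Mid1. DNA linked to the Nfkbia, Nfkbib and Nfkbie loci is argued against as the whole cause, since 6 of them lie on chromosomes without any of the 3 loci, and 0 of the 8 lie within 10 Mb of a locus, against 258 of 8376 others. Gdpd3 lies 98.01 Mb from Nfkbib. For Gm10503 (6.50 log2 units), named here after its values were seen, linkage stays open, since it lies on chromosome 17 only 14.64 Mb from Nfkbie. Of the tested genes within 10 Mb of a locus 22.5% were called, against 15.9% elsewhere (two-sided Fisher exact p = 0.0074). A strain segment on chromosome 11, where 3 of them lie between 83065752 and 83711348, cannot be told apart from regulation, since 12% of 25 neighbouring genes were called against 15.9% elsewhere (two-sided Fisher exact p = 0.787), and such a segment need not change its neighbours. Chemokine, Wfdc and NF-κB target genes were left out of these neighbours, and with them 6 of 31 (19.4%) were called, against 16.0% elsewhere (two-sided Fisher exact p = 0.62). Regulation by NF-κB may be a biological explanation and was not tested.

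Fold changes that differed between classes in the interaction test numbered 123 larger and 151 smaller in lymphoid-like than in HSC-like cells, against 0 and 0 without the pool block (765 unadjusted by edgeR) and 12 and 14 with classes of at least 20 cells, an alternative chosen after seeing the data. The largest positive differences in log2 units were those of Synpo2 (4.22), Ighv1-77 (4.02), Ly6d (3.92), Il7r (3.51) and Tmem121 (3.21). Il7r, the interleukin 7 receptor, was at −3.37 in HSC-like and 0.21 in lymphoid-like cells, and Ly6d, an early lymphoid surface marker, at −1.13 and 3.02. The largest negative differences were those of Tmem158 (−2.89), Emcn (−2.75), Abca1 (−2.69), Pacsin1 (−2.62) and Oas3 (−2.49). In the HSC-like class the genotypes lay mostly in different clusters. At resolution 1.5 a lymphoid-like cluster with Tmem158 among its leading genes held 86 and 198 WT but 3 and 0 IkBKO cells. The interaction was not refitted with the clustering without called genes, so these differences may also compare different cells.

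In megakaryocyte/erythroid-like cells 3 genes had a larger and 2 a smaller fold change than in HSC-like cells, against 0 and 0 in either alternative (280 unadjusted by edgeR without the block and 408 with classes of at least 20 cells). Hist1h2bc (0.89) and Myc (0.73) had larger values and Sdsl (−0.87) had a smaller one. Myc was at −0.49 in HSC-like and 0.22 in megakaryocyte/erythroid-like cells. The split of the HSC-like class by genotype limits these values too. Cmah, chosen after its values were seen, was the fifth gene (adjusted p = 0.046), with 0 WT UMIs in the megakaryocyte/erythroid-like class.

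The CD48 antibody tag, which no comparison used, had a median of 568 counts per cell in IkBKO and 475 in WT cells of replicate 1. By class its ratio, IkBKO over WT, ran from 0.946 in erythroid-like to 1.30 in unnamed cells. Over all cells the Flt3 and CD150 tags had ratios of 0.96 and 0.982. These tags hardly followed their RNA across cells (Spearman correlation 0.065 and 0.083, against 0.44 for CD48). In WT cells the median Flt3 tag was 128 in lymphoid-like and 122 in megakaryocyte/erythroid-like cells, although Flt3 RNA was at 313 and 4.4 CPM. The Flt3 and CD150 ratios thus say little about surface protein. Barcodes left out by the submitters in replicate 2 had a median of 1969 UMIs, against 8201 in those kept.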

How the results depend on the processing

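Leaving out the top doublet scores, class tests with the clustering without called genes, scaling the clustering within pools, re-weighting to one class composition, leaving out the mature and other-lineage classes and the minimum of 20 cells were chosen after seeing the data, and the other alternatives were planned. Of the fold changes of named genes over all alternatives, 5544 were kept, 1304 kept their direction but no longer passed and 101 newly passed. Another 440, all from 1 replicate alone, moved, and 34 reversed. Kept means the same direction and side of the threshold. A single replicate has no test, so kept there (199 values without replicate 1, 202 without replicate 2) means within 1 SE of the first estimate, and moved means by more. A sign change of a value that passed nowhere is counted as kept. Of the list calls 130 were kept and 55 no longer passed. The cause was not tested where none is given.

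Every count of genes over all LSK cells and in the 3 classes stayed within 1.5 times its value under several alternatives. These were RLE size factors, the stricter cell filter, leaving out doublets, and leaving out mitochondrial, ribosomal and haemoglobin genes. No named gene reversed under them. Yet leaving out the 1 called doublet of 18029 cells gave 952 higher and 823 lower genes over all LSK cells. Of the 1964 first calls 1775 were shared, so these counts shift with 1 cell. Without the replicate block, over all LSK cells 0 genes were higher and 0 lower by edgeR (1410 unadjusted; DESeq2 with the block 963 and 601), in HSC-like cells 43 and 25, in lymphoid-like cells 116 and 159 and in megakaryocyte/erythroid-like cells 18 and 11. The interaction counts were 0 in both classes (765 and 280 unadjusted), and the phase differences of 9.91 and 21.2 points over all and in lymphoid-like cells had adjusted p = 0.31 and 0.075. DESeq2 gave 170 and 104 genes in HSC-like, 51 and 40 in lymphoid-like and 23 and 3 in megakaryocyte/erythroid-like cells. With no filter on low counts 1796 genes were higher and 1385 lower over all LSK cells. A mean of at least 10 CPM, which tests fewer genes, gave 304 higher genes in lymphoid-like cells and 0 with a larger fold change in megakaryocyte/erythroid-like than in HSC-like cells (655 unadjusted by edgeR). Pools thinned to one total, which lowers the depth, gave 192 and 210 in lymphoid-like and 134 and 66 in megakaryocyte/erythroid-like cells. With classes of at least 20 cells, 12 and 14 genes had larger and smaller fold changes in lymphoid-like cells and 0 and 0 in megakaryocyte/erythroid-like cells (1138 and 408 unadjusted by edgeR).

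With an estimated correlation camera called 0 lists higher and 0 lower over all LSK cells and in each of the 3 classes. The phase differences were 13 and 23.2 points with 2500 UMIs (adjusted p = 0.097 and 0.35) and 12.5 and 24.4 points without thinning (adjusted p = 0.078 for both), for all LSK and lymphoid-like cells.

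Re-weighted pools gave 216 higher and 229 lower genes, and Tnfaip2 (−0.058), Ms4a2 (−0.25), F13a1 (−0.25) and Ccr2 (−0.88) reversed without passing. Pools without the mature and other-lineage classes gave 550 and 469, with S100a8 (0.021) and Mmp8 (0.29) reversed. Clustering scaled within pools gave 106 and 145 genes in lymphoid-like and 450 and 345 in megakaryocyte/erythroid-like cells. In HSC-like cells it reversed Mpo (1.41, adjusted p = 9.7e-09), F13a1 (1.36), Cebpa (0.24), Cpa3 (0.23) and Cdkn1c (−0.0037), and Mpo was also reversed in the clustering without called genes (0.56, adjusted p = 1.9e-06).

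Against the first clustering, where the ratios of 5.85 for dendritic/monocyte-like, 9.02 for erythroid-like and 6.40 for myeloid-like cells did not pass, those of 5.20, 8.31 and 4.26 with clustering scaled within pools passed, as did 6.21, 8.01 and 5.76 in the clustering without called genes. At resolution 1.5 those that newly passed were 0.091 for HSC-like, 0.19 for lymphoid-like, 2.85 for mast/basophil-like, 3.23 for megakaryocyte/erythroid-like and 7.10 for myeloid-like cells. That HSC-like ratio leaves out an unnamed, mostly IkBKO cluster whose best name was HSC-like. The erythroid-like ratio was only 1.66 at resolution 1.5 (adjusted p = 0.18), where 69.9% of the erythroid-like cells of the clustering without called genes took the megakaryocyte/erythroid-like name, with its ratio of 3.23, and 9.42 at resolution 0.5 (adjusted p = 0.093). The HSC-like and lymphoid-like ratios were 0.27 and 0.19 at resolution 0.5 (adjusted p = 0.082 and 0.063). The neutrophil-like ratio of 0.72 reversed to 2.41 at resolution 1.5 (adjusted p = 0.023) and 2.61 with clustering scaled within pools (adjusted p = 0.041). In the first clustering, without replicate 1 and without replicate 2, the ratio was 12.2 and 2.87 for dendritic/monocyte-like, 19.1 and 4.71 for erythroid-like, 8.61 and 4.81 for myeloid-like, 2.77 and 2.89 for mast/basophil-like and 1.59 and 0.30 for neutrophil-like cells. In the clustering without called genes it was 14.8 and 2.72 for dendritic/monocyte-like, 16.2 and 4.27 for erythroid-like and 4.54 and 7.04 for myeloid-like cells. For T/NK-like cells of that clustering it was 0.92 and 0.24.

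Leaving out each pool in turn removes the block, assumes that the lone pool of a genotype varies like the others, and gave 9 to 59 higher and 16 to 77 lower genes over all LSK cells, 36 to 66 and 13 to 43 in HSC-like, 64 to 130 and 94 to 215 in lymphoid-like, and 1 to 88 and 0 to 47 in megakaryocyte/erythroid-like cells; the 0 came from edgeR without WT replicate 1 or WT replicate 2 (561 and 434 unadjusted). Fold changes that reversed in at least 1 of these settings are given with the range over them. Over all LSK cells they were Ndufb1-ps (−0.21 without IkBKO replicate 1, to 1.13), Rpl36 (−0.082 without IkBKO replicate 1, to 0.59), Rpl41 (−0.066 without IkBKO replicate 1 and −0.0021 without WT replicate 2, to 0.68), Tsix (3.75 without WT replicate 1 and 0.46 without IkBKO replicate 2, from −5.24) and Mmp8 (0.45 without WT replicate 1, from −3.02). In HSC-like cells they were Hlf (0.0052 without IkBKO replicate 1 and 0.020 without WT replicate 2, from −0.97), Rpl36 (−0.032 without IkBKO replicate 1, to 0.56), mt-Co3 (3.4e-04 without WT replicate 1, from −0.27) and S100a8 (0.42 without WT replicate 1 and 0.16 without IkBKO replicate 2, from −1.48). In lymphoid-like cells they were Ly6c2 (−0.81 without IkBKO replicate 1, to 3.36) and Vpreb1 (−0.14 without IkBKO replicate 2 and −0.069 without replicate 2, to 1.89). In megakaryocyte/erythroid-like cells they were Ndufb1-ps (−0.25 without IkBKO replicate 1 and −0.092 without WT replicate 2, to 0.83), Rpl36 (−0.042 without IkBKO replicate 1, to 0.64), S100a9 (−1.40 without IkBKO replicate 1, adjusted p = 0.042, to 0.99), Nfkbia (0.013 without WT replicate 2, from −0.92) and Car2 (0.038 without WT replicate 2, from −0.78). A single replicate leaves no spread between pools, so it gives values and no test, and the smallest pools of 146 and 167 cells limit the depth behind the class counts.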

Other observations

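Classes with at least 20 but under 50 cells in a pool were tested after seeing the data. Dendritic/monocyte-like IkBKO cells had 17 of 29 NF-κB target genes higher and 2 lower (camera adjusted p = 1.1e-13, and adjusted p = 0.77 with an estimated correlation) and 10 of 14 antigen presentation genes higher. IkBKO cells of this class lay mostly in a cluster led by Cd74 and H2-Eb1 (126 and 243 IkBKO against 3 and 1 WT cells), and WT cells mostly in 2 others (37 and 21, then 18 and 4 WT cells, against 45 and 46, then 7 and 60 IkBKO cells), so these values also compare different clusters. The counts for this list in the other classes, which were not tested against this one, were 8 higher and 3 lower of 32 in HSC-like, 4 and 4 of 26 in lymphoid-like, 1 and 2 of 26 in megakaryocyte/erythroid-like and 1 and 0 of 27 in myeloid-like cells. Of 8283 genes 351 were higher and 235 lower in dendritic/monocyte-like cells (smallest pool 26 cells; DESeq2 42 and 25). Leaving out 1 pool gave 111 and 66 (WT replicate 1), 181 and 104 (IkBKO replicate 1), 70 and 39 (WT replicate 2) and 173 and 108 (IkBKO replicate 2). Myeloid-like cells had 20 higher and 20 lower genes (smallest pool 41 cells; DESeq2 6 and 21; edgeR without the block 1 and 1), with 0 of 20 myeloid priming genes higher and 1 lower (camera adjusted p = 3.9e-05, and adjusted p = 0.90 with an estimated correlation) and 5 of 26 interferon genes higher. Of 7 monocyte and dendritic cell genes 2 were lower there and of 6 mature neutrophil genes 2 were lower (adjusted p = 1.4e-13 and 1.0e-09, and adjusted p = 0.90 for both with an estimated correlation). In replicate 2 this class also compares different clusters, since 30 WT and 99 IkBKO cells lay in one led by Ly6c2 and 11 and 288 in one led by Ctsg. Leaving out WT replicate 1 gave 23 higher and 85 lower genes there.

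Among 8 immunoglobulin heavy chain variable genes tested in lymphoid-like cells, on chromosome 12 between 114764450 and 116000461, 3 were higher and 4 lower, a pattern noticed after the values were seen. Ighv1-85 had 0 UMIs in WT and 520 in IkBKO cells, at least 265.0-fold higher against a floor of 3 counts over the group, and Ighv1-82 had 143 and 0, at least 31.1-fold lower. Of the 8 genes, 4 had no UMI in IkBKO cells and 1 had none in WT cells. These genes are near-identical copies, so the assignment of their UMIs is uncertain. Whether the DNA here differs between the genotypes, as asked for the chromosome 11 segment, was not tested.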
